A study of Mus musculus with 11 samples.

How the data were processed

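The data were single-colour microarrays of total RNA from 11 samples of the mouse T-ALL line 720, in 3 compound groups of 3, 4 and 4 arrays. Per the labels' protocols, RNA was isolated with the RNeasy kit, amplified with the Ambion WT Expression Kit and fragmented and labelled with biotin after an Affymetrix GeneChip whole-transcript manual. The submitters' processing notes name RMA and Partek 6.6. The deposited table holds 1 value per probe set and array, which were read as log2 because they range from 3.23 to 13.8 with array medians between 6.61 and 6.68, as RMA output does. The genome build behind the authors' annotation was not given in the sources used here, and no coordinates are printed. All columns of the table belonged to a mapped sample. No background level per probe set was used, so a low value is a dim signal and not an absence.

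Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 were unnamed here. Symbols were updated through the Entrez identifier, for which 23328 of the 23521 were found in a gene table of assembly GRCm38.p6. Each of 22180 genes was represented by its probe set with the highest mean over all arrays, and 1082 genes had more than 1. Of called genes with several probe sets, all probe sets had the same sign in 58 of 81 between AI-8-45 and AI-7-54, in 152 of 207 between AI-9-54 and AI-7-54, and in 20 of 25 between AI-9-54 and AI-8-45. No filter on dim genes was applied.

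The 3 pairwise comparisons came from 1 model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 11 arrays, which share 1 estimate of the spread (8 residual degrees of freedom, prior 4.14). The tests were two-sided, p-values were adjusted with Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. A total of 30 gene lists (679 members, 593 resolved) covering the RUNX and TAL1 circuit, T-cell identity, stress, growth and metabolism programmes and markers of other cell types were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation and limma's fry, which asks whether the genes of a list move on balance one way, were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

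Comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per comparison, the 8 called genes with the largest difference in each direction whose groups do not overlap, leaving out predicted, clone, microRNA, small nucleolar RNA and receptor-family symbols. It added up to 3 called genes from each shifted list in the direction of the shift, the genes Runx1, Runx2, Runx3, Cbfb, Tal1, Tcf12, Myb and Myc, and 5 genes per direction for each compound apart from both others. Wars and Satb1 are named in addition because each was the only called gene of its list in the other direction, and Cbfa2t3 as the only called gene of the RUNX factor list, choices made after their values were seen. The alternatives were 2 other scalings, 2 filters on dim genes, the mean over a gene's probe sets or every probe set, an intensity trend in the prior, array weights, the replicate number as a block, only the groups compared, and each array left out in turn. Added after seeing the data were the replicate set (1 and 2 against 3 and 4) as a fixed factor, and each set by itself.

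The method was tested on simulated data with 200 changed genes among 22180. For AI-9-54 against AI-8-45 it recovered 44% of changes of 0.25 on the log2 scale, 92% of changes of 0.5 and 98% of changes of 1, with 5.65% of calls false, and changes of 2 were recovered at 100% in every comparison. For AI-8-45 against AI-7-54 the shares were 42%, 98% and 100%, with 5.03% false, and for AI-9-54 against AI-7-54 they were 38%, 100% and 100%, with 5.59% false. A shift of 0.2 put into the proteasome list between AI-9-54 and AI-7-54 was called, and 0 of the other lists were. The simulated noise was independent between genes and held no difference between replicate sets. These runs therefore do not test the list calls or the share of false calls where genes are correlated. Sharing between compounds was set against 20 simulations of unchanged groups.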

Results

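Gene expression was measured on microarrays in the mouse T-cell acute lymphoblastic leukaemia (T-ALL) line 720, which the labels trace to a mouse heterozygous for Tcf12 that carries a Tal1 transgene driven by the Lck promoter. Cultures were exposed for 8 h to 1 of 3 compounds that the labels call Runt domain inhibitors, the Runt domain being the DNA-binding part of the RUNX transcription factors. AI-7-54 was given at 100 µM (3 arrays, replicates 1, 3 and 4), AI-8-45 at 100 µM (4 arrays) and AI-9-54 at 50 µM (4 arrays). No vehicle-treated sample was analysed here, so each value below sets a compound against another compound and none is a response to treatment. The compounds carry code names only. The labels do not say whether the replicates of a group were separate cultures, so the gene p-values measure the spread between these arrays, which may be technical. The camera p-values set the genes of a list against all other genes. At the preset correlation of 0.01 they treat those genes as nearly independent, so their size does not measure precision over the arrays. Array medians lay between 6.61 and 6.68 on the log2 scale, and the number of arrays limits the precision.

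The arrays separated by compound along the first principal component (36.2% of the variance). AI-7-54 lay at -17.4 to -14.6, AI-8-45 at -0.416 to 1.41 and AI-9-54 at 10.4 to 11.9. The second component (19.6%) separated replicates 1 and 2 from replicates 3 and 4 in every group, and the third (11.2%) set AI-8-45 replicate 3 apart at 16.3. Median levels were 6.15 for B-lineage markers, 6.24 for myeloid, 6.47 for erythroid and 6.86 for stromal and endothelial markers, at percentiles 34.7 to 49.2 of all genes. The median of 24 genes of T-cell identity was 10.5 (percentile 89.8). None of the 4 marker lists was shifted in any comparison, and none of their measured genes passed the test.

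**Figure D1:**
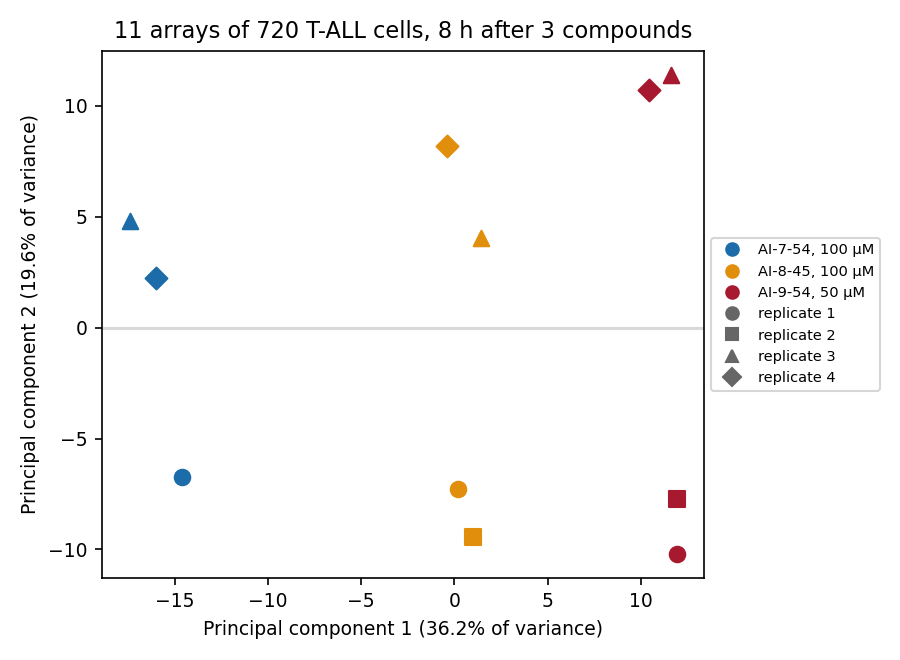
Position of each of the 11 arrays on the first 2 principal components (36.2% and 19.6% of the variance), with colour for the compound and symbol for the replicate number. The horizontal axis orders the compounds, and replicates 1 and 2 lie below 0 on the vertical axis while replicates 3 and 4 lie above it.

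The first comparison asked how AI-8-45 differed from AI-7-54 at the same dose of 100 µM. Genes of cholesterol synthesis and ribosome production were lower after AI-8-45, and their list calls held with an estimated correlation. Of 19 measured cholesterol synthesis genes, 16 were lower and none higher (18 lower when adjusted over the list alone), with a median log2 difference of -0.68. Among them were the squalene epoxidase gene Sqle (10.02 ± 0.06 against 11.09 ± 0.13, SD, a log2 difference of -1.07 with an adjusted p of 1.93e-05), the sterol monooxygenase gene Msmo1 (8.97 ± 0.10 against 9.97 ± 0.15, adjusted p 2.79e-05) and the lanosterol demethylase gene Cyp51 (-1.03, adjusted p 3.47e-05). Of 31 genes of ribosome biogenesis and MYC-driven growth, 26 were lower and none higher (28 lower when adjusted over the list alone), with a median of -0.47. The pyrimidine synthesis gene Cad was lower by a log2 difference of -0.60 ± 0.04 (SE), the spermidine synthase gene Srm by -0.68 ± 0.06 and the RNA polymerase I subunit gene Polr1a by -0.47 ± 0.04. The cholesterol and ribosome lists were shifted by limma's camera test (adjusted p 3.76e-33 and 1.34e-38), and both kept their call with an estimated correlation (adjusted p = 0.0103 for each, and 0.0449 for each with the replicate set, 1 and 2 against 3 and 4, in the model). On all 4 AI-8-45 arrays the mean of either list lay below all 3 AI-7-54 arrays. The medians within replicates 1 and 2 and within replicates 3 and 4 were -0.57 and -0.70 for cholesterol synthesis and -0.40 and -0.47 for ribosome biogenesis.

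In the same comparison, 12 of 31 DNA replication genes were lower (21 when adjusted over the list alone), including the cell-cycle transcription factor gene E2f1 (-0.45), the thymidine kinase gene Tk1 (-0.44, adjusted p 0.00182) and the cyclin gene Ccne1 (-0.37). Heat shock genes were lower in 5 of 18 (11 lower and 1 higher when adjusted over the list alone). They were led by Hspa1b, which encodes an inducible HSP70 chaperone (6.83 ± 0.20 against 8.78 ± 0.32, SD, a 3.86-fold lower level, adjusted p 2.96e-05), with its neighbour Hspa1a at -0.64 and Fkbp4 at -0.52. Transcripts of Hspa1a and Hspa1b are near-identical, so their values are uncertain as separate genes. Proteasome genes were lower in 5 of 30 (17 when adjusted over the list alone), with Psmc5 at -0.32, Psmc1 at -0.24 and Psmd13 at -0.22. Genes of nuclear-encoded oxidative phosphorylation were lower in 2 of 34, Cox5a at -0.28 (-0.17 within replicates 1 and 2) and Sdhb at -0.23, with the same count when adjusted over the list alone. Chaperones of the unfolded protein response were lower in 2 of 21 (4 when adjusted over the list alone), Hyou1 at -0.34 and Sdf2l1 at -0.24. These 5 lists were shifted down in the camera test, with medians of -0.25 for replication, -0.24 for heat shock, -0.15 for proteasome, -0.11 for oxidative phosphorylation and -0.10 for chaperones, and in each list mean all 4 AI-8-45 arrays lay below all 3 AI-7-54 arrays. The medians within replicates 1 and 2 and within 3 and 4 were -0.22 and -0.25 for replication, -0.14 and -0.23 for heat shock, -0.12 and -0.16 for the proteasome, -0.09 and -0.09 for oxidative phosphorylation, and -0.06 and -0.10 for chaperones. All 5 lost the call with an estimated correlation, with adjusted p = 0.36 for replication, proteasome and oxidative phosphorylation, adjusted p = 0.319 for heat shock and adjusted p = 0.371 for chaperones. The chaperone call also ended without AI-7-54 replicate 3 (adjusted p 0.0509) or AI-8-45 replicate 3 (median -0.05, adjusted p 0.0511). Leaving out 1 array ended the gene calls of Cox5a, Sdhb, Psmc1, Psmd13 and Sdf2l1 in 3 to 6 of 11 cases (adjusted p 0.0508 to 0.113).

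Large single-gene differences were also found outside these lists. Tceal1 (probe set 17537936) was 3.81-fold higher after AI-8-45 (9.56 ± 0.10, SD, n = 4, against 7.63 ± 0.06, n = 3, limma adjusted p 1.03e-08), and Abcb1b, a gene for the multidrug efflux pump P-glycoprotein, was 2.15-fold higher (adjusted p 2.79e-05). Higher by a log2 difference under 1 were Gpr171 (0.83, and 0.55 as the mean of its probe sets), Rundc3b (0.80), Zfp563 (0.79) and the interferon-inducible GTPase gene Gbp4 (0.77). So were the histone gene H2aw (0.76) and Mfsd4b3-ps (0.76, not called in 4 of 11 cases with 1 array left out, adjusted p up to 0.136). Bex6 (probe set 17324745) was lower by a log2 difference of -2.87 (5.68 ± 0.45, SD, n = 4, against 8.55 ± 0.33, n = 3, limma adjusted p 2.79e-05). Its mean after AI-8-45 lay below the array medians and no background level was used, so no fold is given for it. The same holds for Tat, Gzmb and Nrp2 below, whose lower mean lay there too. Mfsd4b3-ps (mean 6.16 after AI-7-54) and Hspa1a (mean 6.56 after AI-8-45) also had their lower mean there. The stearoyl-CoA desaturase gene Scd1 (-1.14) and the endothelial lipase gene Lipg (-0.96) were also lower, as was the lanosterol synthase gene Lss of the cholesterol list (8.71 ± 0.20 against 9.71 ± 0.04). In all, limma called 1255 of 22180 genes at an adjusted p under 0.05, 473 higher and 782 lower, and 10 differed at least 2-fold. The count fell to 540 without AI-7-54 replicate 3 and to 622 without AI-7-54 replicate 4. It was 1949 with the replicate set in the model, 2 within replicates 1 and 2, where AI-7-54 has 1 array, and 613 within replicates 3 and 4.

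The next comparison set AI-9-54 at 50 µM against AI-7-54 at 100 µM, so compound and dose cannot be separated. The ribosome biogenesis and cholesterol synthesis lists were again lower. The integrated stress response, NRF2, immediate early and autophagy lists were higher and the heat shock list was lower, calls that were all lost with an estimated correlation (adjusted p = 0.442 to 0.693). Of 31 ribosome biogenesis genes, 29 were lower and none higher, with the same count when adjusted over the list alone (median -0.57, camera adjusted p 2.45e-33), among them Cad (-0.78 ± 0.04, SE), Srm (-0.97 ± 0.06) and the nucleolar phosphoprotein gene Nolc1 (-0.75 ± 0.05). Of 19 cholesterol synthesis genes, 17 were lower and none higher, again with the same count over the list alone (median -0.68, camera adjusted p 5.39e-22), with Sqle at -1.29, Msmo1 at -1.06 and the dehydrocholesterol reductase gene Dhcr7 at -0.67. On all 4 AI-9-54 arrays the mean of either list lay below all 3 AI-7-54 arrays. The medians within replicates 1 and 2 and within 3 and 4 were -0.52 and -0.60 for ribosome biogenesis and -0.65 and -0.66 for cholesterol synthesis. Both calls held with an estimated correlation (adjusted p = 0.0328 and 0.0369). They were lost with an estimated correlation and the replicate set in the model (adjusted p = 0.126 for each).

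Genes of the integrated stress response, which cells switch on when translation initiation is restrained, were higher after AI-9-54 than after AI-7-54 in 10 of 38 cases and lower in 1, and 14 were higher and 1 lower when adjusted over the list alone (median 0.28). With the replicate set in the model 20 were higher and 3 lower. The transcription factor gene Atf5 was 2.15-fold higher (9.23 ± 0.17, SD, n = 4, against 8.12 ± 0.10, n = 3, limma adjusted p 4.34e-06), Ddit3, which encodes CHOP, was 2.71-fold higher (adjusted p 6.89e-05) and Vldlr 2.12-fold (adjusted p 0.000551). The gene that was lower without the set in the model was Wars, a tryptophanyl-tRNA synthetase gene (-0.42). The level of this list also depended on the replicate set. Over both sets its mean lay above all 3 AI-7-54 arrays on 2 of 4 AI-9-54 arrays (mean difference 0.40, 95% interval -0.07 to 0.87). On all 4 it lay above the AI-7-54 arrays of the same set (0.33, 0.25 to 0.40 with the set in the model). That interval may be too narrow, since the set was chosen because it separated these arrays. The median difference of the list was 0.27 within replicates 1 and 2 and 0.14 within replicates 3 and 4. Genes of the NRF2 oxidative response were higher in 7 of 24 and lower in 3 (11 and 3 when adjusted over the list alone, median 0.22), with the glutathione synthesis gene Gclc at 0.56, Abcc1 at 0.46 (0.26 within replicates 1 and 2) and Mafg at 0.27. Immediate early genes were higher in 7 of 28 and lower in 2 (8 and 2 over the list alone, median 0.14), with the AP-1 gene Fosl2 at 1.37, Klf6 at 0.41 and Jund at 0.41. Autophagy and lysosome genes were higher in 7 of 29 and lower in none (10 and 2 over the list alone, median 0.07), with Fnip1 at 0.41, Mcoln1 at 0.29 and Atg14 at 0.35. The means of the NRF2, immediate early and autophagy lists lay above all 3 AI-7-54 arrays on all 4 AI-9-54 arrays. Their medians within replicates 1 and 2 and within 3 and 4 were 0.09 and 0.30, 0.01 and 0.20, and 0.07 and 0.12. The camera adjusted p was 2.95e-05 for the integrated stress response, 0.0148 for NRF2 and for immediate early genes, and 0.0118 for autophagy. All 4 upward calls were lost with an estimated correlation, with adjusted p = 0.693 for the integrated stress response and adjusted p = 0.644 for the others. With fry the integrated stress response, NRF2 and immediate early lists missed the threshold as well (adjusted p 0.124, 0.0652 and 0.0755). The NRF2 call also ended without AI-7-54 replicate 4 (adjusted p 0.0567) or AI-9-54 replicate 3 (median 0.14, adjusted p 0.06), the immediate early call without AI-7-54 replicate 4 (0.159) and the autophagy call without AI-9-54 replicate 3 (median 0.02, adjusted p 0.0588). With the calls kept, the immediate early median was 0.07 without AI-9-54 replicate 3, and the autophagy median was 0.11 without AI-9-54 replicate 1 and 0.03 without its replicate 4.

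Lists of DNA replication, oxidative phosphorylation, proteasome and heat shock genes were lower after AI-9-54 than after AI-7-54, with list means of all 4 AI-9-54 arrays below all 3 AI-7-54 arrays. DNA replication genes were lower in 11 of 31 (15 over the list alone, median -0.25), with Tk1 at -0.50, Uhrf1 at -0.49 and E2f1 at -0.42. Oxidative phosphorylation genes were lower in 11 of 34 (22 over the list alone, median -0.15), with Cox5a at -0.40, Ndufa2 at -0.36 and Sdhb at -0.34. Proteasome genes were lower in 13 of 30 (19 over the list alone, median -0.18), with Psmc5 at -0.34, Psmd3 at -0.26 and Psmd13 at -0.26. Heat shock genes were lower in 7 of 18 (11 over the list alone, median -0.29), with Hspa1b at -1.48, Fkbp4 at -0.61 and Hspa4 at -0.29 (-0.15 within replicates 1 and 2). Medians within replicates 1 and 2 and within 3 and 4 were -0.23 and -0.16 for replication, -0.15 and -0.14 for oxidative phosphorylation, -0.19 and -0.14 for the proteasome, and -0.24 and -0.22 for heat shock. These calls were lost with an estimated correlation, with adjusted p = 0.644 for replication, adjusted p = 0.311 for oxidative phosphorylation, adjusted p = 0.46 for the proteasome and adjusted p = 0.442 for heat shock. T-cell identity genes were lower in 7 of 24 and higher in 2 (8 and 2 over the list alone, median -0.07), but the list missed the threshold (camera adjusted p 0.0706). The 27 mitosis genes, none called (8 lower with the replicate set in the model), missed it too (median -0.12, adjusted p 0.0519). Under 25 alternatives T-cell identity passed in 7, fry among them (adjusted p 0.00167 to 0.644 over all), and mitosis in 11 (0.000304 to 0.807). With the replicate set in the model these lists and the hypoxia and glycolysis list passed (adjusted p 0.0106, 0.0334 and 0.00373). None of them held with an estimated correlation as well (adjusted p = 0.299, 0.573 and 0.463). Chaperones of the unfolded protein response (2 higher and 4 lower of 21, median -0.04, adjusted p 0.281) and the TAL1 regulatory circuit (1 higher and 3 lower of 17, median -0.02, adjusted p 0.519) missed the threshold. The TAL1 circuit passed under 1 of 25 alternatives, downward with fry (adjusted p 0.021, and up to 0.761 over the others).

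The largest differences between AI-9-54 and AI-7-54 were those of Tceal1, 6.02-fold higher (10.22 ± 0.08, SD, n = 4, against 7.63 ± 0.06, n = 3, limma adjusted p 2.96e-10), and Slc7a11, the cystine and glutamate exchanger gene, 5.15-fold higher (10.38 ± 0.28, SD, against 8.02 ± 0.75, adjusted p 0.00383, with a log2 difference of 2.36, or 1.24 as the mean of its probe sets). Abcb1b was 4.37-fold higher (adjusted p 3.95e-08) and Plaur, the urokinase receptor gene, 4.03-fold (adjusted p 2.2e-06). The tyrosine aminotransferase gene Tat (2.19) and the granzyme B gene Gzmb (1.93) were higher on the log2 scale, with a spread among the AI-9-54 arrays (SD 1.32 and 1.09) that followed the replicate set. The log2 difference of Tat was 1.44 within replicates 1 and 2 and 3.13 within replicates 3 and 4, that of Gzmb 1.24 and 2.74, and both passed with the set in the model (adjusted p 0.000118 and 5.3e-05). Without the set their calls ended without AI-7-54 replicate 1 (adjusted p up to 0.0721 for Tat, whose call also ended without AI-7-54 replicate 4, and 0.0599 for Gzmb). The alkaline ceramidase gene Acer2 (3.08-fold) and the long non-coding RNA Neat1 (2.91-fold) followed. Lower were Bex6 (-2.20), the terminal deoxynucleotidyl transferase gene Dntt (-1.40, adjusted p 0.00132), the Src-family kinase gene Blk (-1.35, adjusted p 1.22e-05), Lipg (-1.25), the small RNA gene Rny3 (-1.20, not called without AI-7-54 replicate 4, adjusted p 0.083) and the fatty acid binding protein gene Fabp5 (-1.19). In all, 3139 of 22180 genes passed limma's test, 1523 higher and 1616 lower, and 57 differed at least 2-fold, 36 of them higher. Within replicates 1 and 2, where AI-7-54 has 1 array, the count was 593, and within replicates 3 and 4 it was 2189.

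**Figure D2:**
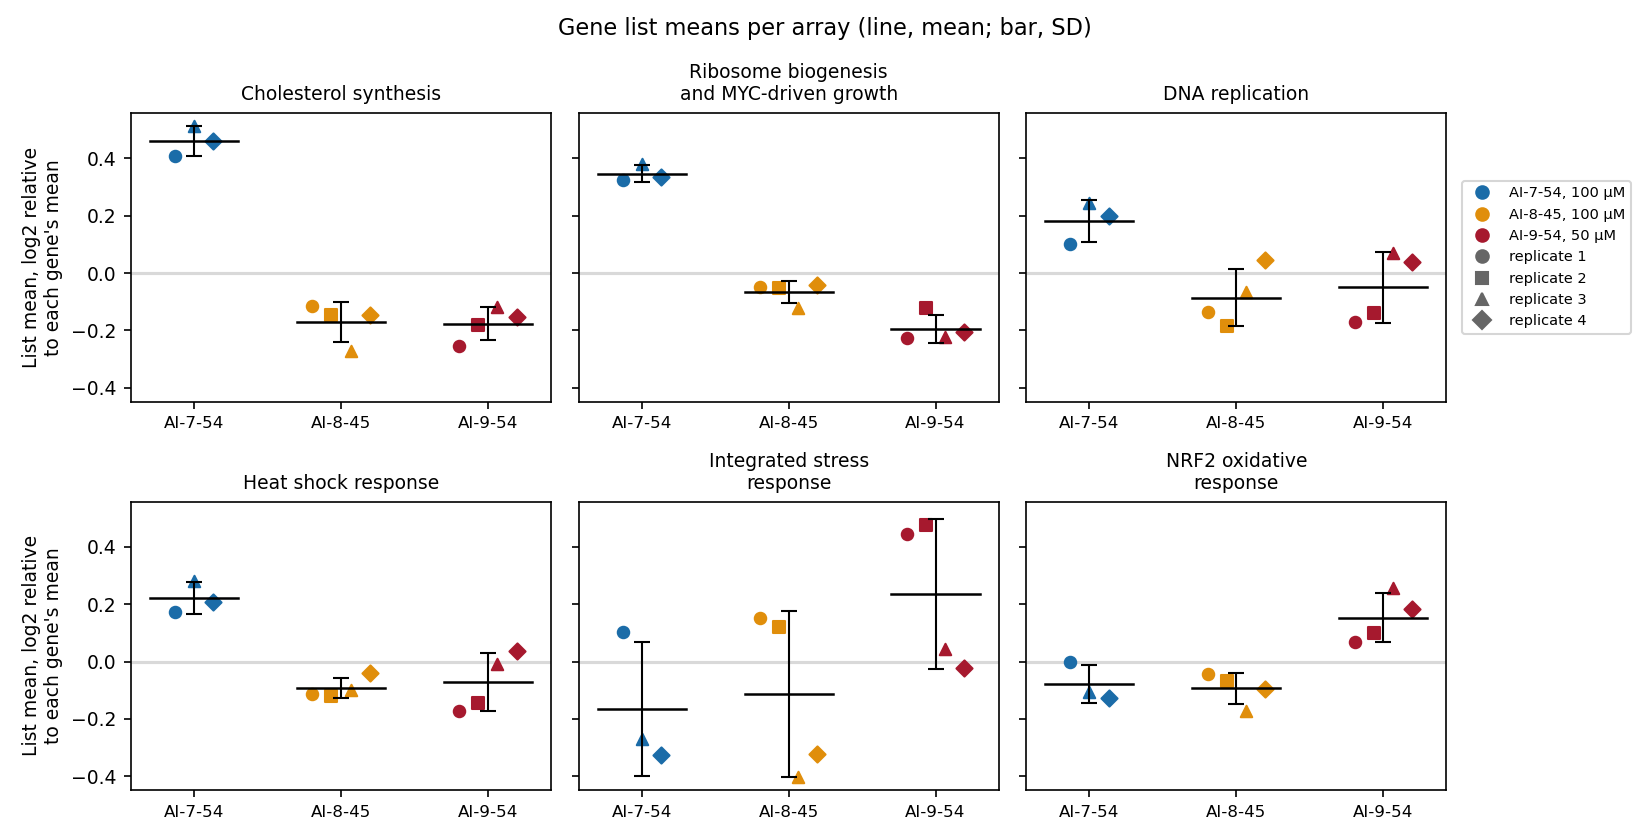
Mean of 6 gene lists on each array, as log2 relative to each gene's mean over the 11 arrays (vertical axis), by compound (horizontal axis), with symbols for the replicate number, a line for the group mean and bars for the SD. The cholesterol and ribosome means of all 3 AI-7-54 arrays lie above those of the other 8 arrays, and the integrated stress response means lie higher in replicates 1 and 2 than in replicates 3 and 4 in each group.

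The last pairwise comparison set AI-9-54 at 50 µM against AI-8-45 at 100 µM, where again compound and dose cannot be separated. The integrated stress response, NRF2, immediate early and autophagy lists were higher after AI-9-54, and the T-cell identity and ribosome lists were lower, with few genes called in each without the replicate set in the model. None of these list calls held with an estimated correlation (adjusted p = 0.615, 0.315, 0.802 and 0.615 for the higher lists and adjusted p = 0.297 for each of the lower ones), and with fry the higher lists missed the threshold too (adjusted p 0.221, 0.051, 0.221 and 0.215). No heat shock gene of 18 and no unfolded protein response chaperone of 21 was called (camera adjusted p 0.971 and 0.356). In the integrated stress response list 3 of 38 genes were higher and none lower (9 higher over the list alone), with a median of 0.28 that was 0.28 within replicates 1 and 2 and 0.32 within replicates 3 and 4. With the replicate set in the model 23 were higher and none lower. Over both sets the list mean lay above all 4 AI-8-45 arrays on 2 of 4 AI-9-54 arrays (mean difference 0.35, 95% interval -0.08 to 0.78). On all 4 it lay above both AI-8-45 arrays of the same set (0.35, 0.28 to 0.42 with the set in the model). The set was chosen because it separated these arrays, so that interval may be too narrow and the count of 23 too high. The 3 genes called without the set were Slc7a11 (3.87-fold, 10.38 ± 0.28 against 8.43 ± 0.98, SD, n = 4 each, limma adjusted p 0.045), Ddit3 (1.80-fold, adjusted p 0.0157) and Atf5 (1.72-fold, adjusted p 0.000322). The log2 difference of Slc7a11 was 1.95, or 1.34 within replicates 1 and 2, 2.56 within replicates 3 and 4 and 1.03 as the mean of its probe sets, with an adjusted p of 0.00017 with the set in the model. NRF2 genes were higher in 6 of 24 and lower in none (12 and 1 over the list alone, median 0.17), with Gclc at 0.44, Gclm at 0.33 and the thioredoxin reductase gene Txnrd1 at 0.39 (0.28, 0.20 and 0.24 within replicates 1 and 2). Immediate early genes were higher in 3 of 28 and lower in 1 (5 and 1 over the list alone, median 0.09), with Fosl2 at 1.10, Klf6 at 0.78 and Dusp1 at 0.44. In the autophagy and lysosome list 1 of 29 genes was higher (2 over the list alone, median 0.05), the autophagy receptor gene Sqstm1 at 0.25. Sqstm1 is also in the NRF2 list, and Slc7a11 is in both the integrated stress response and NRF2 lists, so these lists are not separate evidence. Medians within replicates 1 and 2 and within 3 and 4 were 0.09 and 0.30 for NRF2, 0.02 and 0.10 for immediate early genes, and 0.03 and 0.05 for autophagy. Leaving out 1 array ended the immediate early call without AI-8-45 replicate 2 (adjusted p 0.0595), 3 (median 0.05, adjusted p 0.14) or 4 (0.164) and without AI-9-54 replicate 2 (0.0577) or 3 (median 0.06, adjusted p 0.0562). It ended the autophagy call without AI-8-45 replicate 2 (0.0595) and AI-9-54 replicate 3 (median 0.03, adjusted p 0.0859) or 4 (0.0532). The NRF2 median was 0.11 without AI-9-54 replicate 3, with the call kept. It also ended the gene calls of Slc7a11, Dusp1, Txnrd1 and Sqstm1 in 8 to 10 of 11 cases (adjusted p 0.0511 to 0.121), of Gclm without AI-8-45 replicate 3 (0.0508) or 4 (0.0566), and of Ddit3 without AI-8-45 replicate 4 (0.0515).

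T-cell identity genes were lower after AI-9-54 than after AI-8-45 in 3 of 24 cases and higher in 1 (5 and 2 over the list alone, median -0.06). Lower were Bcl11b, a transcription factor gene of T-lineage commitment (11.77 ± 0.05 against 12.18 ± 0.05, SD, n = 4 each, limma adjusted p 0.000678), the surface glycoprotein gene Thy1 (-0.37) and Dntt (-1.02), and the gene that was higher was Satb1 (0.35). Ribosome biogenesis genes were lower in 4 of 31 and higher in none (16 and 1 over the list alone, median -0.13), with Nolc1 at -0.26, Srm at -0.30 and Ppan at -0.34 (-0.21 within replicates 1 and 2). None of the 27 mitosis genes (median -0.11), 34 oxidative phosphorylation genes (median -0.08) or 17 genes of the TAL1 regulatory circuit (median -0.04) passed the test by itself, while these lists were shifted down (camera adjusted p 0.000248, 3.07e-05 and 0.0414). With the replicate set in the model 5 mitosis genes were lower, 1 TAL1 circuit gene was higher and 3 were lower, and no oxidative phosphorylation gene was called. The medians within replicates 1 and 2 and within 3 and 4 were -0.06 and -0.07 for T-cell identity, -0.13 and -0.12 for ribosome biogenesis, -0.13 and -0.09 for mitosis, -0.08 and -0.05 for oxidative phosphorylation and -0.08 and -0.02 for the TAL1 circuit. Over the list alone, 3 TAL1 circuit genes were lower and no mitosis or oxidative phosphorylation gene was called. These 5 list calls did not hold with an estimated correlation, with adjusted p = 0.297 for the ribosome, T-cell and TAL1 lists, adjusted p = 0.544 for oxidative phosphorylation and adjusted p = 0.82 for mitosis, and with fry oxidative phosphorylation and mitosis missed the threshold too (adjusted p 0.215 and 0.667). With the replicate set in the model as well, the integrated stress response list passed (adjusted p = 0.0362). The mitosis call ended without AI-8-45 replicate 4 (adjusted p 0.0519) or AI-9-54 replicate 1 (0.0899), and the median was -0.06 without either of these or without AI-9-54 replicate 2. The TAL1 call ended without AI-8-45 replicate 1 (0.0841), 2 (0.0866) or 3 (0.0605) or AI-9-54 replicate 1 (0.0899). Leaving out 1 array ended the gene calls of Dntt, Ppan and Srm in 5 to 9 of 11 cases (adjusted p 0.0514 to 0.122) and that of Nolc1 without AI-8-45 replicate 1 (0.051).

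No cholesterol synthesis gene of 19 was called between AI-9-54 and AI-8-45 (2 lower over the list alone). The median was 0.00103 while the mean and the camera test pointed down (mean -0.01, 95% interval -0.11 to 0.09, camera adjusted p 0.731). For 31 DNA replication genes the mean difference was 0.04 (-0.13 to 0.20, adjusted p 0.242, none called), and for 18 heat shock genes it was 0.02 (-0.10 to 0.14, adjusted p 0.971, none called) with a median of -0.02. With the set in the model the intervals were -0.11 to 0.10 for cholesterol synthesis, -0.04 to 0.11 for DNA replication and -0.06 to 0.10 for heat shock. These may be too narrow, since the set was chosen because it separated the arrays. Cholesterol synthesis passed downward under 1 of 25 alternatives, within replicates 1 and 2 (adjusted p 0.00618), DNA replication upward under 5 (from 0.00174) and heat shock under none. The p-values do not show that the compounds act alike on those genes. Notch targets and targets of the aryl hydrocarbon receptor missed the threshold (medians -0.13 and 0.09, adjusted p 0.354 and 0.0527), and passed under 3 and 10 of 25 alternatives. Both passed with the replicate set in the model (adjusted p 0.0167 and 0.0148), and both calls were lost with an estimated correlation as well (adjusted p = 0.215 and 0.222). Mitosis genes passed upward with the set between AI-8-45 and AI-7-54 (adjusted p 0.0133, against 0.757 without the set), a call also lost with an estimated correlation (adjusted p = 0.685).

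Outside the lists, Plaur was 2.68-fold higher after AI-9-54 than after AI-8-45 (9.33 ± 0.30 against 7.90 ± 0.09, SD, n = 4 each, limma adjusted p 0.000163), Acer2 2.09-fold, Abcb1b 2.04-fold (adjusted p 9.78e-05), Neat1 1.87-fold (not called in 7 of 11 cases with 1 array left out, adjusted p up to 0.0969) and the neuropilin gene Nrp2 by a log2 difference of 0.89 (0.53 within replicates 1 and 2). The acyl-CoA thioesterase gene Acot5 (-0.93), Fstl4 (-0.83), the adhesion receptor gene Adgrg1 (-0.80), the growth factor gene Tgfb3 (-0.73), Elfn2 (-0.70), the serine protease gene Prss57 (-0.63) and Clec11a (-0.62, not called without AI-8-45 replicate 1, adjusted p 0.0516) were lower. In all, 290 of 22180 genes passed limma's test, 157 higher and 133 lower, and 6 differed at least 2-fold. The count was 816 with the replicate set in the model, which included all 290. It was 6 within replicates 1 and 2 and 143 within replicates 3 and 4. It was 517 with the replicate block, 436 among genes above the median level and 141 with only the compared groups. It was 189 without AI-7-54 replicate 4, 128, 152, 160 and 137 without AI-8-45 replicates 1, 2, 3 and 4, and 184, 148 and 174 without AI-9-54 replicates 2, 3 and 4. With each of the 41345 probe sets tested by itself, 129 probe sets passed, which is not a count of genes.

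**Figure D3:**
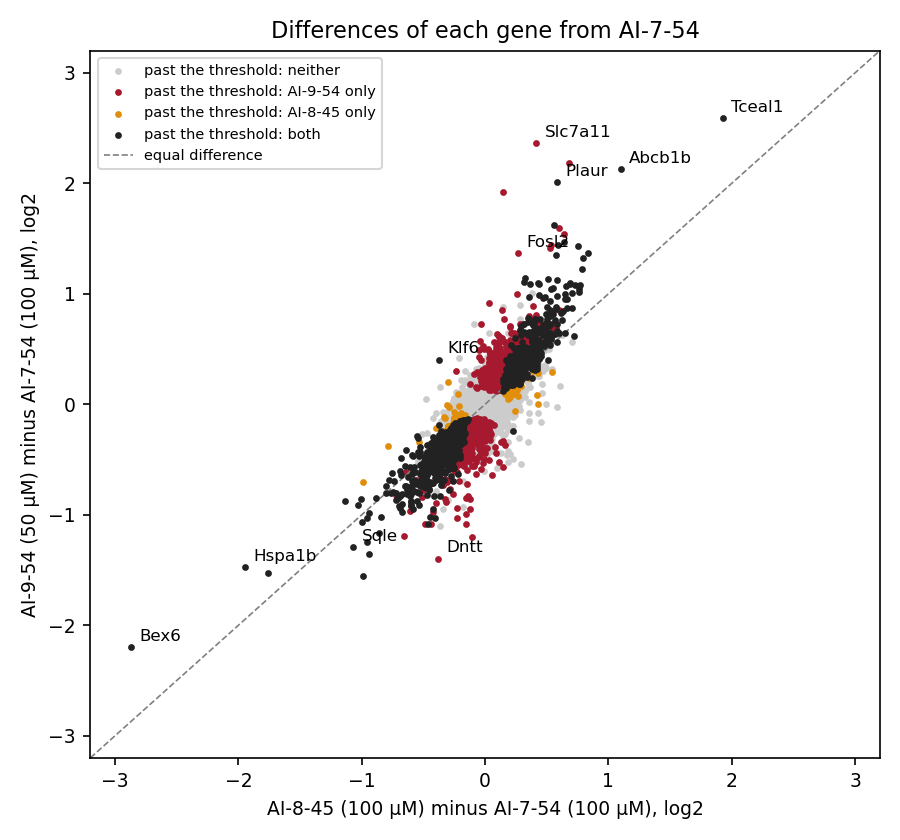
Log2 difference of each gene between AI-8-45 and AI-7-54 (horizontal axis) and between AI-9-54 and AI-7-54 (vertical axis), coloured by which of the comparisons passed an adjusted p under 0.05, with a dashed line of equal difference. Both axes share the AI-7-54 arrays, and 1159 genes passed in both with the same sign.

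Genes were then counted that set a compound apart from both others. AI-7-54 stood apart at 1159 genes, 722 higher and 437 lower than after both other compounds, including 26 of the 31 ribosome genes, 16 of the 19 cholesterol genes and 11 of the 31 replication genes on the higher side. The largest on the higher side were Bex6, Hspa1b, Sqle, Msmo1 and Lipg, and on the lower side Tceal1, Abcb1b, Gpr171 (8.55 ± 0.08, SD, n = 3, against 9.38 and 9.91), Rundc3b (10.39 ± 0.06 against 11.18 and 11.71) and Zfp563 (8.97 ± 0.09 against 9.75 and 10.19). AI-9-54 stood apart at 269 genes, 148 higher and 121 lower, with Slc7a11, Plaur, Fosl2, Acer2 and Abcb1b leading the first group and Dntt, Acot5, Fstl4, Adgrg1 and Tgfb3 the second. AI-8-45 stood apart at 9 genes. Spo11, the antiproliferative gene Btg2, Ksr2 and a gene with a predicted symbol, left unnamed by the rule for named genes, were higher than after both others. Klf6 (10.02 ± 0.12, SD, n = 4, against 10.40 and 10.80), Klf7, Oser1, the chemokine receptor gene Ccr2 and the stress sensor gene Ern1 were lower. Leaving out 1 array gave 519 and 590 for AI-7-54 (without its replicates 3 and 4) and 2 to 5 for AI-8-45 without AI-7-54 replicate 3 or 4, AI-8-45 replicate 1 or 4, or any AI-9-54 array. For AI-9-54 it gave 169 without AI-7-54 replicate 4, 119, 144, 152 and 130 without AI-8-45 replicates 1, 2, 3 and 4, and 178, 141 and 166 without AI-9-54 replicates 2, 3 and 4. Within replicates 1 and 2 the counts were 2 for AI-7-54, 0 for AI-8-45 and 6 for AI-9-54, and within replicates 3 and 4 they were 569, 7 and 135. With the replicate set in the model 36 genes set AI-8-45 apart and 715 AI-9-54, and with the replicate block 19 and 452. With every probe set tested by itself, 5 probe sets set AI-8-45 apart and 119 AI-9-54. Among genes above the median level, 405 set AI-9-54 apart. Unchanged groups simulated against the same shared arrays gave 0 genes in each of 20 simulations. That was nearly fixed in advance, since almost no gene is called without an effect, so it does not measure sharing among real differences. Independent lists of the same lengths would share 57 higher and 32.5 lower genes for AI-7-54, 10.8 and 9.69 for AI-9-54, and 2.84 and 5.54 for AI-8-45. With the shared arrays split, the mean count was 110 for AI-9-54 and 1.33 for AI-8-45, and the 3 AI-7-54 arrays could not be split. The split comparisons used fewer arrays, so their lower counts mix lost power with the loss of sharing. The part of the excess due to shared arrays was therefore not measured for AI-7-54 or AI-9-54. For AI-8-45 the counts, 4 higher and 5 lower, lay near those of independent lists, so there was little excess.

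**Figure D4:**
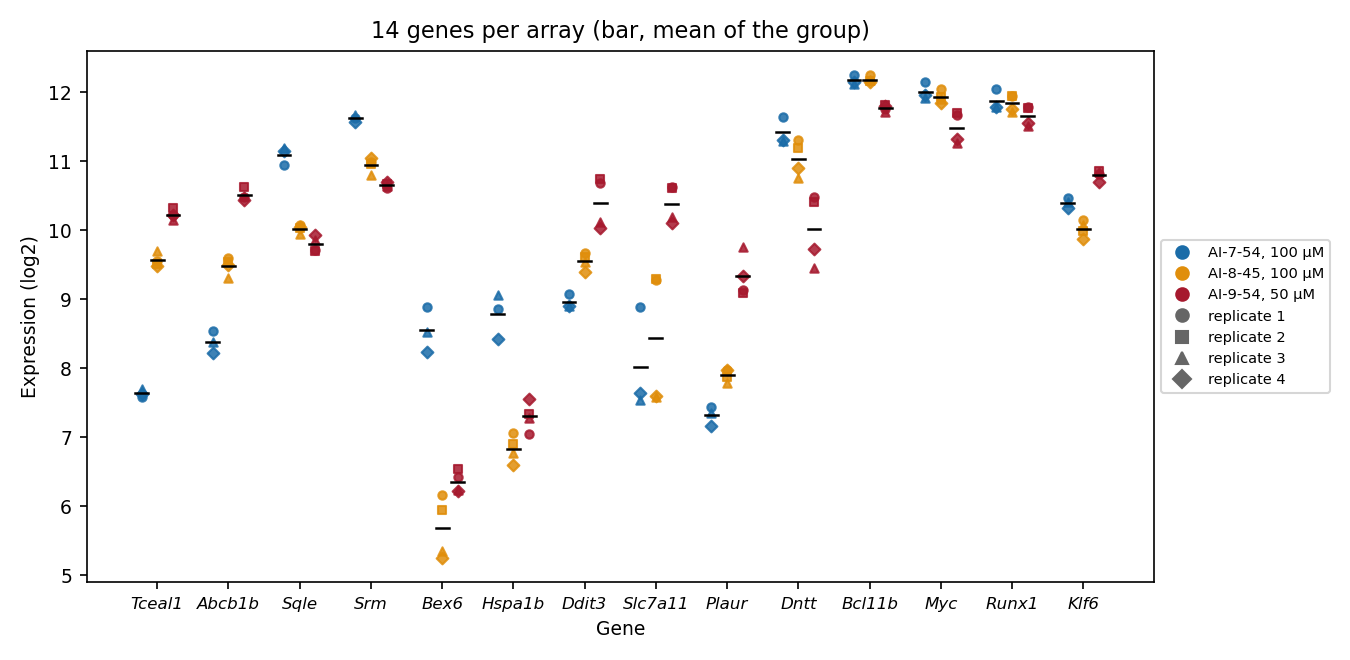
Expression (log2, vertical axis) of 14 genes (horizontal axis) on each of the 11 arrays, with colour for the compound, symbol for the replicate number and a short bar for the group mean. Tceal1 and Abcb1b rise from AI-7-54 through AI-8-45 to AI-9-54, and Slc7a11 lies higher in replicates 1 and 2 than in 3 and 4 after AI-7-54 and AI-8-45.

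Because the compounds are named for the Runt domain, the genes of the RUNX and TAL1 transcription complex were read in every comparison. Runx1 was highly expressed after each compound (11.87 ± 0.14 after AI-7-54, 11.83 ± 0.12 after AI-8-45 and 11.65 ± 0.14 after AI-9-54, SD, n = 3, 4 and 4). Its log2 difference was -0.04 between AI-8-45 and AI-7-54 (95% interval -0.24 to 0.16, adjusted p 0.929), -0.22 between AI-9-54 and AI-7-54 (-0.42 to -0.02, adjusted p 0.157) and -0.18 between AI-9-54 and AI-8-45 (-0.37 to 0.00, adjusted p 0.444). With the replicate set in the model, a choice made after seeing the data, both AI-9-54 differences of Runx1 passed limma's test (-0.26, adjusted p 0.000445, and -0.18, adjusted p 0.0119). They also passed with the replicate block, and in all under 3 and 2 of 23 alternatives, over which the adjusted p reached 0.483 and 0.658. Myb was lower after AI-9-54 than after AI-7-54 (12.40 ± 0.03 against 12.64 ± 0.01, SD, adjusted p 0.0014), as was Myc (-0.52 ± 0.11, SE, adjusted p 0.00573), calls that held under 21 and 22 of 23 alternatives. Against AI-8-45 the Myc difference of -0.44 (95% interval -0.66 to -0.23) missed the threshold with an adjusted p of 0.0519 and passed it with the replicate set in the model (adjusted p 0.000897, the lowest of 23 alternatives, with 9 passing and the highest at 0.239). The Myb difference of -0.14 against AI-8-45 missed it too (95% interval -0.21 to -0.06, adjusted p 0.0997, and 0.022 to 0.466 over the alternatives, with 3 passing). Neither gene passed between AI-8-45 and AI-7-54 (Myb -0.10, 95% interval -0.18 to -0.02, and Myc -0.08, 95% interval -0.31 to 0.16).

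Runx3, Cbfb, Tal1 and Tcf12 did not pass in any comparison. Under 1 of 23 alternatives each, Tal1 passed between AI-9-54 and AI-7-54 (adjusted p 0.0447 to 0.334 over the alternatives) and Tcf12 between AI-9-54 and AI-8-45 (0.0377 to 0.563). Between AI-9-54 and AI-7-54 the 95% intervals were -0.15 to 0.20 for Runx3, -0.06 to 0.10 for Cbfb, -0.36 to -0.05 for Tal1 (adjusted p 0.078) and -0.12 to 0.06 for Tcf12. Between AI-8-45 and AI-7-54 they were -0.30 to 0.04, -0.14 to 0.03, -0.23 to 0.07 and 0.02 to 0.19, and between AI-9-54 and AI-8-45 they were 0.00 to 0.31, 0.00 to 0.15, -0.27 to 0.02 and -0.21 to -0.05. The labels do not say whether the Tal1 probe set reads the transgene, and Runx2 had no probe set named for it alone here. The list of 6 RUNX factors and partners and the 19 haematopoietic genes with known RUNX sites missed the threshold between AI-8-45 and AI-7-54 (medians -0.05 and 0.02, camera adjusted p 0.421 and 0.757), AI-9-54 and AI-7-54 (-0.02 and -0.01, 0.631 and 0.576) or AI-9-54 and AI-8-45 (0.000827 and -0.03, 0.971 and 0.396). For the RUNX-site genes the mean had the other sign between AI-8-45 and AI-7-54 (-0.06, as the test) and between AI-9-54 and AI-8-45 (0.03). For the RUNX factors it was -0.07, as the test, in the latter. All 4 AI-8-45 arrays lay below all 3 AI-7-54 arrays in the mean of the RUNX factors, and all 4 AI-9-54 arrays lay below all arrays of both other compounds. The only called RUNX factor gene was the corepressor gene Cbfa2t3, between AI-9-54 and AI-7-54 (-0.89, adjusted p 0.00325), named after its value was seen. There 3 of the 6 genes were higher and 3 lower, so the list mean of -0.16 leaned on Cbfa2t3. Of the 19 RUNX-site genes, 2 were called lower between AI-8-45 and AI-7-54 and none between AI-9-54 and AI-8-45. Between AI-9-54 and AI-7-54, 1 was called higher (Gzmb, 1.93) and 3 lower, Blk among them (-1.35). In the mean of the RUNX-site genes all 4 AI-8-45 arrays lay below all 3 AI-7-54 arrays and below all 4 AI-9-54 arrays. The mean differences had 95% intervals of -0.15 to -0.04, -0.22 to -0.10 and -0.12 to -0.02 for the RUNX factors and -0.10 to -0.01, -0.07 to 0.02 and -0.01 to 0.07 for the RUNX-site genes, in the same order. With fry, which does not set a list against other genes, the RUNX-site list passed downward between AI-9-54 and AI-7-54 (adjusted p 0.022, the only pass under 25 alternatives, against 0.697 with an estimated correlation). The RUNX factors passed downward under 1 alternative, between AI-8-45 and AI-7-54 within replicates 1 and 2 (adjusted p 0.0294). Notch targets missed the threshold as well (adjusted p 0.347, 0.913 and 0.354 in the same order). Between AI-9-54 and AI-7-54 their median was -0.08 while the mean was 0.00374.

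The remaining lists missed the camera test's threshold in every comparison with all arrays and no replicate set in the model, and their values are given for AI-9-54 against AI-7-54, the comparison with most called genes. Interferon response genes had a median of 0.09 (8 of 24 higher and 3 lower, adjusted p 0.0768), NF-kB targets 0.15 (5 of 18 higher and 1 lower, adjusted p 0.153) and hypoxia and glycolysis genes 0.08 (5 of 29 higher and 1 lower, adjusted p 0.141). The p53 targets had 4 genes higher and 4 lower of 23 (adjusted p 0.633), the BCL2 family 1 higher and 2 lower of 15 (adjusted p 0.408), and the metal response 2 higher and 2 lower of 8 (adjusted p 0.74). Targets of the aryl hydrocarbon receptor had 1 higher and 1 lower of 8 (adjusted p 0.83), those of the liver X receptor with lipid desaturation 2 higher and 5 lower of 12 (adjusted p 0.406), and replication-dependent histones 2 higher and 1 lower of 12 (median -0.02, mean 0.00107, adjusted p 0.703). Some of these lists passed under a few of 25 alternatives. Between AI-9-54 and AI-7-54 the interferon and hypoxia lists passed under 5 each and NF-kB targets, the BCL2 family and liver X receptor targets under 1 each, the last 2 with fry (adjusted p 0.022 upward and 0.021 downward). Between AI-8-45 and AI-7-54 liver X receptor targets passed under 4 (with fry at 0.0176), interferon and NF-kB under 3 each, hypoxia under 2 and histones under 1, and of lists called elsewhere the integrated stress response and immediate early genes under 2 each, upward with array weights or without AI-7-54 replicate 1. Between AI-9-54 and AI-8-45 hypoxia passed under 4, interferon under 1 and the proteasome, called elsewhere, under 2, and the p53 targets had a median of -0.02 and a mean of 0.00475.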

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

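The tests on the replicate sets' stress genes, on the common position with the replicate set in the model, on the stress genes within replicates 1 and 2, on the order of the compounds in replicates 3 and 4 or by single arrays, and on splits within the replicate sets for the comparisons with AI-7-54, were chosen after the results were seen. The mean of the ribosome biogenesis list was 9.96 on AI-8-45 replicate 3, against 10.03 to 10.04 on the other 3 arrays of the group. Its gap to the nearest array was 0.866 of the group's range, above Dixon's critical value at 95%. It was the only one of 190 values tested to pass, where chance alone would give about 5% in each group.

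AI-8-45 lay between the other compounds at most genes that separate AI-7-54 from AI-9-54. Genes picked and measured on the same arrays could give such an order, but of 2244 genes picked on replicates 3 and 4, 78.3% also had AI-8-45 in between on replicates 1 and 2, where AI-7-54 has 1 array (69.0 to 74.9% with 1 array per compound), above the bound set beforehand, which argues against that source. In the reverse order AI-7-54 and AI-9-54 alone gave 0 genes on replicates 1 and 2, and 593 genes were then picked with the spread of all 5 arrays of the set, AI-8-45 included, of which 79.6% had AI-8-45 in between on replicates 3 and 4 (67.6 to 84.5% with 1 array per compound). A further test asked whether AI-8-45 lay at the same relative position between AI-7-54 and AI-9-54 at every gene. No vehicle was analysed and the doses differed, so this position does not measure the strength of a compound. The test set in advance left the question undecided. At a limma adjusted p under 0.05, 21 genes left the common position, between the bounds of 10 and 50 set beforehand. With the replicate set in the model, 169 genes left it, which argues against the same position at every gene. That model was chosen after the 21 (Klf6 and Bex6 among them) were seen.

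Replicates 1 and 2 differed from replicates 3 and 4 at 1569 genes, 708 higher and 861 lower, and the highest of the other splits among 100 was 836. The sets were picked because they separated the arrays, so neither this count nor the intervals below can exclude chance. The integrated stress response was higher in replicates 1 and 2 in 3 of 3 compound groups, with a mean of 0.46 (95% interval 0.40 to 0.52), and what raised it, such as amino acid supply, was not tested. Stress of the endoplasmic reticulum would also raise chaperones, and their mean of 0.00961 (-0.03 to 0.05) argues against it. The labels do not say what a replicate number stands for, and the design names no group that tells the sets apart, so a difference of day, passage or culture density stays open.

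The integrated stress response was higher after AI-9-54 than after AI-8-45. Without AI-8-45 replicate 3 the median difference was 0.20, at the bound of 0.2 set beforehand and with an SD of 0.11 when a further array was left out, so that test does not decide whether this array is the source. Within replicates 1 and 2, which leave it out, the difference was 0.282 (limma camera adjusted p 6.86e-21), which argues against that array as the only source. The smaller of the differences within the replicate sets was also 0.282, which argues against an unequal mix of the sets, as does the design, where both compounds hold 2 arrays of each set. The difference in dose between the compounds cannot be told apart from the compound, and the call was lost with an estimated correlation (adjusted p = 0.615).

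For the counts of genes, 1 of 35 splits of the arrays gave as many as the 1255 between AI-8-45 and AI-7-54 (highest other 3) and as the 3139 between AI-9-54 and AI-7-54 (highest other 1), the real split in both. Those shares lay under the bound of 0.05 set beforehand, which argues against chance. They are the smallest that 35 splits allow, and the splits ignore the replicate sets, so chance is not excluded. With the set in the model, the real splits gave 1949 and 4036 genes and the highest of the others within the sets 0 and 1 (1 of 18 splits in each). Between AI-9-54 and AI-8-45, 2 of 35 splits gave at least 290, and the other, with 500 genes, parted replicates 1 and 2 of both groups from replicates 3 and 4, so chance cannot be excluded without the replicate set. With the set in the model, the real split gave 816 genes and the highest of the others within the sets gave 0 (1 of 18 splits), but in all 3 comparisons 18 splits are too few for a share under 0.05.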

How the results depend on the processing

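The replicate set as a factor and each set by itself were chosen after seeing the data. Between AI-9-54 and AI-8-45 the 290 genes became 436 among genes above the median level. They became 141 with only the compared groups, 816 with the replicate set, 6 within replicates 1 and 2, and 143 within replicates 3 and 4. With 1 array left out they were 128 (without AI-8-45 replicate 1) to 257. With every probe set tested by itself, 129 probe sets passed, which is not a count of genes. Between AI-8-45 and AI-7-54 the 1255 genes became 1949 with the set, 2 and 613 within the sets, and 540 to 1229 with 1 array left out (540 without AI-7-54 replicate 3, 622 without AI-7-54 replicate 4). Between AI-9-54 and AI-7-54 the 3139 genes became 593 within replicates 1 and 2 and 2103 to 3290 with 1 array left out. Fewer arrays explain the lower counts within the sets in part, and the cause of the other changes was not tested. Genes setting AI-7-54 apart were 2 and 569 within the sets and 519 to 1108 with 1 array left out. Those setting AI-8-45 apart were 36 with the replicate set, 0 within replicates 1 and 2, and 2 to 6 with 1 array left out. Those setting AI-9-54 apart were 405 above the median level, 715 with the replicate set, 6 and 135 within the sets, and 119 to 231 with 1 array left out. With every probe set tested by itself, 5 probe sets set AI-8-45 apart and 119 AI-9-54. Lists shifted between AI-8-45 and AI-7-54 were 11 with array weights, 2 with an estimated correlation and 7 to 11 with 1 array left out. Between AI-9-54 and AI-7-54 they were 2 with an estimated correlation and 9 to 13 with 1 array left out. Between AI-9-54 and AI-8-45 they were 0 with an estimated correlation, 3 with fry (8 and 12 in the other comparisons) and 6 to 11 with 1 array left out. No pairing by replicate number was established. Same-numbered arrays correlated at -0.0225 to 0.451 in their deviations (median 0.13). Arrays of the same set with another number correlated at 0.0404 to 0.492 (median 0.311). In every other group at once, 0 of 11 arrays correlated best with their own number. AI-7-54 replicate 1 and AI-8-45 replicate 1 did correlate best with each other (0.451), so pairing of some arrays stays open. With the replicate block, 517 genes differed between AI-9-54 and AI-8-45, 19 set AI-8-45 apart and 452 set AI-9-54 apart, and the other counts stayed within 1.5 times. Regulator values that had not been called changed sign. Between AI-8-45 and AI-7-54, Runx1 was 0.016 with array weights and -0.078 (without AI-7-54 replicate 4) to 0.047 (without AI-7-54 replicate 1) with 1 array left out, 0.007 without AI-8-45 replicate 3, and Tal1 was -0.125 (without AI-7-54 replicate 1) to 0.01 (without AI-7-54 replicate 3) and 0.023 within replicates 1 and 2. Between AI-9-54 and AI-7-54, Runx3 was -0.002 with the replicate block, -0.046 without AI-7-54 replicate 3 and 0.121 without AI-7-54 replicate 1, the ends of its left-out range, -0.025 without AI-9-54 replicate 2, -0.001 with the replicate set and -0.095 within replicates 1 and 2. Cbfb was 0.000 without AI-7-54 replicate 3 to 0.039 without AI-7-54 replicate 1, and -0.042 within replicates 1 and 2, and Tcf12 was 0.017 within replicates 1 and 2. With 1 array left out, the calls of 21 named genes ended in at least 1 case. Signal was lowest for the RUNX-site, aryl hydrocarbon receptor and marker lists, with members' median percentiles of 34.9 to 49.2 among all genes. The other lists lay at 57.7 or above. Among values of named genes under the alternatives, 2614 kept direction and call, 200 lost the call, 19 gained it and 13 changed sign.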

Other observations

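The tests between the replicate sets and those of the FOXO, glucocorticoid receptor and nucleotide synthesis lists were chosen after the results were seen, and those 3 lists were written after genes of the same pathways had been noticed, while the other lists had been fixed beforehand. Beyond the compounds, integrated stress response and mitosis genes differed between the replicate sets, while the ribosome biogenesis list was not shifted (1 of 31 genes higher, adjusted p 0.272). In replicates 1 and 2, 30 of 38 integrated stress response genes were higher than in replicates 3 and 4 and none lower (limma camera adjusted p 8.46e-42, and adjusted p = 0.0107 with an estimated correlation). They were led by the amino acid transporter gene Slc7a3 (1.23), the glutathione-degrading enzyme gene Chac1 (1.17) and Slc7a11 (1.14). The amino acid transporter gene Slc1a4, which is not in the list, was also higher (1.14). Of 27 mitosis genes 25 were lower in replicates 1 and 2 (adjusted p = 0.0235 with an estimated correlation), and 15 of 29 hypoxia and glycolysis genes were lower, including the phosphofructokinase gene Pfkl (-1.11), the triosephosphate isomerase gene Tpi1 (-1.03) and the glucose transporter gene Slc2a1 (-0.68), a call lost with an estimated correlation (adjusted p = 0.172). Notch targets were higher in 8 of 12 and lower in 1, NF-kB targets higher in 4 of 18 and p53 targets in 10 of 23, with none lower in either (adjusted p = 0.0157, 0.0157 and 0.0424 with an estimated correlation). The T-cell identity and immediate early lists (up) and the heat shock, DNA replication, oxidative phosphorylation and proteasome lists (down) also passed, calls lost with an estimated correlation (adjusted p = 0.111 to 0.382). Replicates 1 and 2 include 1 array of AI-7-54, and the differences were fitted with the compound in the model. The sets were picked because they separated these same arrays, so the p-values between them cannot exclude chance.

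The genes Abcb1a, Abcb1b and Abcb4, neighbouring genes of the multidrug transporter family chosen after their values were seen, were highest after AI-9-54. Against AI-7-54 the log2 differences were 1.00 for Abcb1a, 2.13 for Abcb1b and 0.66 for Abcb4, each called by limma (adjusted p 6.01e-06, 3.95e-08 and 4.78e-05). Against AI-8-45 they were 0.74, 1.03 and 0.30, also called (adjusted p 0.000329, 9.78e-05 and 0.0382). Abcb1a and Abcb1b have similar transcripts, so their values are uncertain as separate genes.

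Growth lists were lower after AI-9-54 and AI-8-45 than after AI-7-54. A hypothesis is lower PI3K and mTORC1 signalling, which would lower nucleotide synthesis and raise FOXO targets. Without a vehicle-treated sample, a fall after these compounds cannot be told from a rise after AI-7-54. The ribosome and MYC-driven growth list itself holds the pyrimidine synthesis gene Cad, so lower nucleotide synthesis is not separate evidence. Of 15 measured purine and pyrimidine synthesis genes 13 were lower after AI-9-54 than after AI-7-54 (median -0.37, adjusted p = 0.0185 with an estimated correlation, over 33 lists), and 12 of 21 FOXO targets were higher and none lower, with a median of 0.284 and adjusted p = 8.67e-09 at the preset correlation. The FOXO call was lost with an estimated correlation (adjusted p = 0.0907). After AI-8-45 against AI-7-54, 11 of the 15 synthesis genes were lower (median -0.32, adjusted p = 0.0106 with an estimated correlation), and 4 FOXO targets were higher and 1 lower (median 0.17, adjusted p = 0.215 with an estimated correlation), so the hypothesis stays undecided. Glucocorticoid receptor activity, which Tat might point to, was not resolved either: 2 of 15 targets were higher and 2 lower, and the median of -0.000807 lay below 0 by far less than the members' spread. No protein or signalling state was measured.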
